A study of Bostrychia moritziana with 3 samples.

How the data were processed

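The series holds RNA sequencing libraries of 3 life stages of the red alga Bostrychia moritziana, grown as unialgal cultures of one strain. Per the labels' protocols, male gametophytes were collected while they formed spermatangia, female gametophytes while they formed carpogonial branches, and tetrasporophytes once their sporangia were mature. RNA was extracted with TRI Reagent and made into Illumina libraries, per the labels' protocols. There was 1 library per life stage, so no spread between replicates could be estimated for any value, and no p-value was computed.

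The deposited values are RPKM (reads per kilobase of transcript per 1000000 mapped reads), 1 value per transcript and library, rounded to 2 decimals, per the file headers and the values themselves. The assembler, aligner, counting tool, transcript lengths and read totals are not given in the sources used here. Transcripts carry an assembly number only (ISGT followed by a number), and the files do not pair these numbers with gene names, sequences or functions. The 20 lists of gene families fixed before the data were examined (among them meiosis, phycobilisome, reactive oxygen enzymes and bacterial markers) could therefore not be evaluated, and no gene is named.

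The male and female listings hold the same 30448 transcripts, the tetrasporophyte listing holds 34695, and 28609 are in all 3. The highest number is 43049, and 36534 numbers occur in at least 1 listing. The values show a rule behind the listings. Over the male and female listing, the higher of the male and female value was never below 0.3 RPKM. Every one of the 27832 transcripts above 0.3 RPKM in the male library is also in the tetrasporophyte listing, including 8770 that stand below 0.3 RPKM in the tetrasporophyte. None of the 6086 transcripts listed for the tetrasporophyte only is below 0.3 RPKM there. The listings thus behave as if transcripts below 0.3 RPKM in both male and female, or in both male and tetrasporophyte, had been left out, and a transcript missing from a listing was read as at most 0.3 RPKM. For the female library this reading rests on the male and female listing having 1 rule, which was not tested separately. All 3 listings also contain values of 0, so a missing transcript was never set to 0 in the fold comparisons.

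The main comparison of a pair of libraries used the deposited RPKM without further scaling, over transcripts listed for both with at least 1 RPKM in one of them. The log2 ratio was taken after adding a pseudocount of 1 RPKM, and a transcript was counted as apart at 4-fold, a log2 ratio of 2 in either direction. The log2 ratios of the fold comparisons are on this log2(RPKM + 1) scale, which understates the difference of transcripts with low values. The ratios used for relative depth, and those of the tetrasporophyte to a gametophyte among the closing observations, are of RPKM with no pseudocount. Because the main rule leaves out transcripts missing from a listing, each count was repeated with a missing value set to 0.3 RPKM, which gives the smallest fold the listing rule allows. The overlap of 2 comparisons that share a library was set beside that of independent lists, which does not allow for the shared library.

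Up to 2 transcripts higher and 2 lower per pair were named, those with the largest log2 ratio in each direction, plus the most abundant transcript of each library. This rule, the filter, the pseudocount, the threshold and the alternatives were fixed before the data were examined. The alternatives were median-of-ratios scaling, scaling of each library's sum to 1000000, no filter, a filter of 10 RPKM, a pseudocount of 0.1, thresholds of 2-fold and 8-fold, and only transcripts above 0 in all 3 libraries. The setting of missing values to 0.3 RPKM was added after the data were seen.

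Read totals are unknown, so no counting interval was given for any RPKM value. Relative depth was estimated from the steps of low values: transcripts with the same number of reads in 2 libraries share 1 ratio of RPKM, the inverse ratio of the libraries' read totals. The 3 ratios were fitted jointly, in steps of 0.01 on the log2 scale, over transcripts between 0.3 and 3 RPKM, as the ratio with the largest excess of transcripts over its surroundings. The fit takes the most common step to be that of equal reads. On 20000 simulated transcripts with known read totals it recovered the log2 ratios within 0.003. The counting of transcripts 4-fold apart was tested on simulated data of 28609 transcripts with 200 changed: for each of the 3 pairs, 100% of the 8-fold changes and 0% of the 2-fold changes were counted, with 0 unchanged transcripts counted. The changed transcripts were drawn only from those well above the pseudocount, and the simulated noise was small. This checks the code and does not show how many 8-fold changes of low transcripts are counted. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.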

Results

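Bostrychia moritziana is a red alga in which free-living male and female gametophytes alternate with a free-living tetrasporophyte that bears the spores. The female also carries the carposporophyte after fertilization, a stage that is not analysed here. RNA abundance was measured in 1 library each of male gametophytes, female gametophytes and tetrasporophytes, as RPKM per assembled transcript. The male and female listings each held 30448 transcripts and the tetrasporophyte listing 34695. The median listed transcript stood at 2.55 RPKM in the male, 1.34 RPKM in the female and 1.00 RPKM in the tetrasporophyte. These medians depend on the listings and do not rank the libraries. The 6086 transcripts listed for the tetrasporophyte only had a median of 0.47 RPKM. At least 1 RPKM was reached by 18936 transcripts in the male, 15942 in the female and 17377 in the tetrasporophyte. At least 10 RPKM was reached by 9748, 8768 and 9806 transcripts, respectively, and at least 1000 RPKM by 17 transcripts in each library. With 1 library per stage, every difference below is between these libraries, and its size relative to the spread between replicates is not known.

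The number of reads per library is unknown, but the values moved in steps that give their ratio. Over low transcripts, 71 male to female ratios lay within 0.01 of a log2 ratio of 0.16, against 30 in the windows beside it. The same excess was seen at -0.04 for male to tetrasporophyte (145 against 27.8) and at -0.20 for female to tetrasporophyte (60 against 22). If these are transcripts with equal reads, the female library held 1.12 times and the tetrasporophyte library 0.973 times as many reads as the male library. All 200 bootstrap resamples of the transcripts gave these ratios, which does not test whether the steps are those of equal reads.

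A few transcripts took more of the male library than of the others. The most abundant male transcript, ISGT_41164, stood at 15688 RPKM in the male, 822 RPKM in the female and 369 RPKM in the tetrasporophyte, and made up 3.12% of the summed male RPKM. The most abundant female transcript, ISGT_1443, stood at 3453 RPKM in the female, 644 RPKM in the male and 776 RPKM in the tetrasporophyte. In the tetrasporophyte the most abundant transcript was ISGT_4561, with 3891 RPKM against 366 RPKM in the male and 1125 RPKM in the female. The 10 most abundant transcripts held 7.98% of the summed RPKM in the male, 4.59% in the female and 3.96% in the tetrasporophyte. Of the 100 most abundant transcripts of each library, 41 were shared by male and female, 32 by female and tetrasporophyte, 21 by male and tetrasporophyte, and 15 by all 3. Of the male's 100 most abundant, 40 were at least 4-fold above the female and 53 at least 4-fold above the tetrasporophyte. The tetrasporophyte's 100 included 46 that far above the male and 43 above the female, and the female's 100 included 26 above the male and 38 above the tetrasporophyte.

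Across the 20474 transcripts listed for all 3 libraries with at least 1 RPKM in one of them, the female and the tetrasporophyte had the highest Spearman correlation, 0.85, against 0.79 for male and female and 0.78 for male and tetrasporophyte. Pearson correlations of log2(RPKM + 1) were 0.84, 0.78 and 0.76 in the same order. This set keeps every transcript restricted to the male but leaves out most of those restricted to the female or the tetrasporophyte. With missing values set to 0.3 RPKM and lower values raised to it, the Spearman correlations were 0.81, 0.79 and 0.76 in the same order. Transcripts are not independent replicates, so no test was made. Among transcripts with at least 10 RPKM in one library, the Spearman correlations were lower (0.66, 0.60 and 0.59) and in the same order.

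The first comparison was that of the sexes, male against female gametophytes. Of the 20061 transcripts considered, 1852 (9.23%) were at least 4-fold higher in the male and 647 (3.23%) at least 4-fold higher in the female. The remaining 17562 were less than 4-fold apart, and 13177 (65.7%) were less than 2-fold apart. The male-higher group had a median of 14.19 RPKM in the male and 0.28 RPKM in the female, and held 24.0% of the summed male RPKM but 1.68% of the female's. The female-higher group had a median of 16.98 RPKM in the female and 0.18 RPKM in the male, and held 10.8% of the summed female RPKM. In the male-higher group, 209 transcripts reached 100 RPKM and 420 were listed at 0 in the female. In the female-higher group, 109 reached 100 RPKM and 68 were listed at 0 in the male.

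The largest ratio between the sexes was that of ISGT_12851, with 1737 RPKM in the male, 0.14 RPKM in the female and 0.59 RPKM in the tetrasporophyte, a log2 ratio of male to female of 10.57. ISGT_41944 stood at 691 RPKM in the male and 0.43 RPKM in the female (log2 ratio 8.92), but at 294 RPKM in the tetrasporophyte. On the female side, ISGT_4679 stood at 812 RPKM in the female, 0.88 RPKM in the male and 0.18 RPKM in the tetrasporophyte, a log2 ratio of male to female of -8.76. ISGT_4899 had 585 RPKM in the female, 2.97 RPKM in the male and 0.05 RPKM in the tetrasporophyte, a log2 ratio of -7.21.

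The male excess held at each level of abundance. Between 1 and 10 RPKM, 735 transcripts (7.93%) were 4-fold higher in the male and 211 (2.28%) in the female. The lowest transcripts of this class cannot reach 4-fold with a pseudocount of 1, which lowers these percentages. Between 10 and 100 RPKM the counts were 908 and 327, and at 100 RPKM or more they were 209 and 109. The median log2 ratio of male to female was 0.51 in the lowest of these classes, 0.02 in the middle one and -0.16 in the highest.

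**Figure D1:**
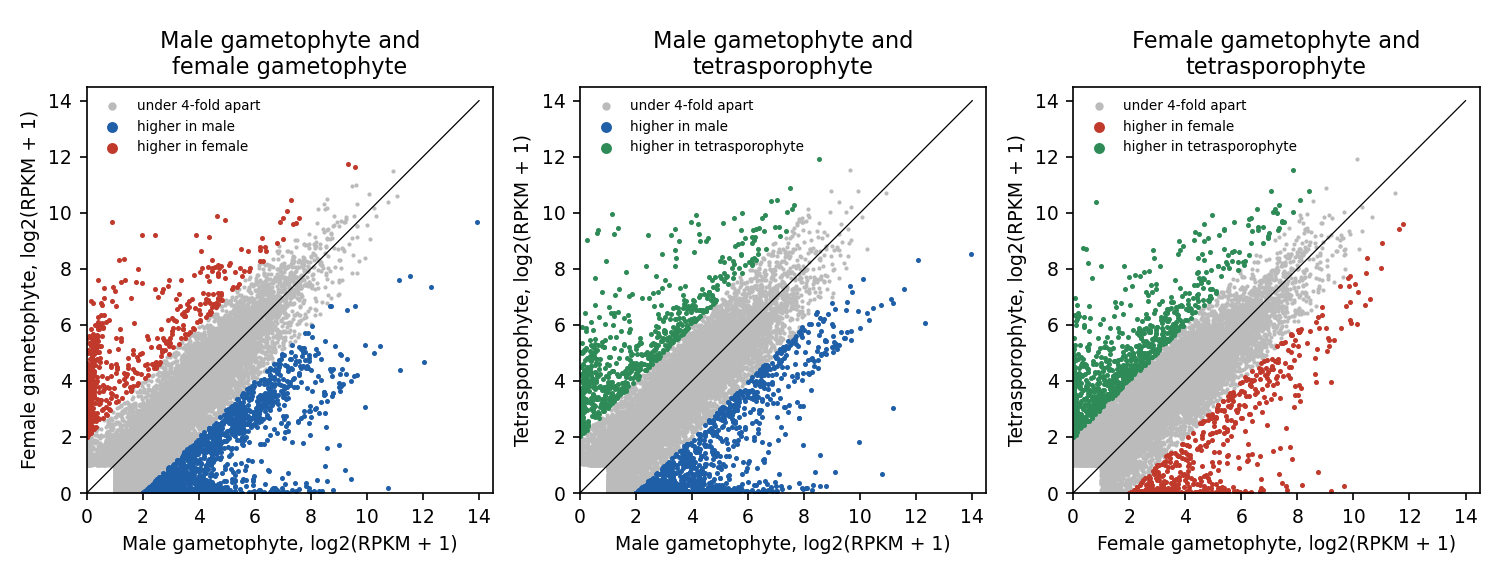
Each point is 1 transcript listed for both libraries with at least 1 RPKM in one of them, and both axes give log2(RPKM + 1). The diagonal marks equal values, coloured points are at least 4-fold apart (1852 and 647 for male and female, 1576 and 688 for male and tetrasporophyte, 602 and 1027 for female and tetrasporophyte), and grey points are less than 4-fold apart.

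The level of these sex-apart transcripts in the tetrasporophyte, the stage that descends from both parents, differed between the 2 groups. All 1852 male-higher transcripts were listed for the tetrasporophyte. There, 1069 (57.7%) were at least 4-fold below the male and 342 (18.5%) at least 4-fold above the female, with a median of 2.06 RPKM. Of the 647 female-higher transcripts, 198 were missing from the tetrasporophyte listing. With these set to 0.3 RPKM, 306 (47.3%) were at least 4-fold below the female and 231 (35.7%) at least 4-fold above the male. Among the 449 that were listed, the median was 11.4 RPKM in the tetrasporophyte and 24.8 RPKM in the female, and 134 (29.8%) were at least 4-fold below the female. The 198 left out here were read as at most 0.3 RPKM in the tetrasporophyte. The median and share of the 449 are therefore not comparable with those of the male-higher group.

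The second comparison was that of each gametophyte with the tetrasporophyte. Against the male, 688 of 20150 transcripts (3.41%) were at least 4-fold higher in the tetrasporophyte and 1576 (7.82%) at least 4-fold higher in the male. The tetrasporophyte-higher group had a median of 26.5 RPKM in the tetrasporophyte and 1.79 RPKM in the male, and held 14.7% of the summed tetrasporophyte RPKM. The male-higher group had a median of 11.9 RPKM and held 23.6% of the summed male RPKM. Transcripts missing from the male and female listing are left out of these counts. With them set to 0.3 RPKM, 1018 transcripts were higher in the tetrasporophyte and 1576 in the male.

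ISGT_12851 had the largest male to tetrasporophyte log2 ratio, 10.09. ISGT_16731 followed with 444 RPKM in the male, 0.08 RPKM in the female and 0.20 RPKM in the tetrasporophyte, a log2 ratio of 8.54. In the opposite direction, ISGT_41943 stood at 986 RPKM in the tetrasporophyte, 320 RPKM in the female and 1.20 RPKM in the male, a log2 ratio of male to tetrasporophyte of -8.81. ISGT_43039 stood at 673 RPKM in the tetrasporophyte, 159 RPKM in the female and 0.55 RPKM in the male, a log2 ratio of -8.76.

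Against the female, 1027 of 17592 transcripts (5.84%) were at least 4-fold higher in the tetrasporophyte and 602 (3.42%) at least 4-fold higher in the female. With missing values set to 0.3 RPKM the counts were 1357 and 774. The tetrasporophyte-higher group had a median of 17.4 RPKM in the tetrasporophyte and 1.19 RPKM in the female, and 189 of its members were listed at 0 in the female. The female-higher group had a median of 21.4 RPKM in the female and 0.51 RPKM in the tetrasporophyte, and 110 of its members were listed at 0 in the tetrasporophyte.

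ISGT_4679 and ISGT_4899, described above on the female side, also had the largest female to tetrasporophyte log2 ratios, 9.43 and 9.13. On the tetrasporophyte side, ISGT_41092 stood at 1343 RPKM in the tetrasporophyte, 599 RPKM in the male and 0.76 RPKM in the female, a log2 ratio of female to tetrasporophyte of -9.58. ISGT_8221 stood at 424 RPKM in the tetrasporophyte, 225 RPKM in the male and 0.27 RPKM in the female, a log2 ratio of -8.39.

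Comparing both gametophytes with the tetrasporophyte, 335 transcripts were at least 4-fold higher in each gametophyte and 307 at least 4-fold lower in each. The second count depends on the listings: with missing values set to 0.3 RPKM it was 637, while the first stayed at 335. With missing values so set, 18068 transcripts passed the filter in both comparisons. Among them, 819 were higher in the male and 567 in the female than in the tetrasporophyte, and independent lists of these sizes would share 25.7. Lower in the male were 1018 and in the female 1357, for which independent lists would share 76.5. Both comparisons use the same tetrasporophyte library, which makes their lists overlap by itself, and the size of that part was not estimated.

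Most of the transcripts that stood apart in 1 library did so in the male. At least 4-fold above each of the other 2 libraries were 1069 transcripts in the male, 134 in the female and 307 in the tetrasporophyte. The male group had a median of 11.5 RPKM and held 17.7% of the summed male RPKM, with 140 members at 100 RPKM or more. The female group was smaller, with a median of 57.3 RPKM, and held 5.47% of the summed female RPKM. The tetrasporophyte group had a median of 33.4 RPKM and held 7.33% of the summed tetrasporophyte RPKM. With missing values set to 0.3 RPKM the female count was 306 and the tetrasporophyte count 637, and the male count was again 1069.

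Transcripts restricted to 1 library were counted as those at or above a given level in it and at most 0.3 RPKM, or missing, in both others. At 1 RPKM there were 2037 such transcripts in the male, 384 in the female and 806 in the tetrasporophyte. At 10 RPKM there were 176 in the male, 98 in the female and 175 in the tetrasporophyte, and at 100 RPKM there were 16, 2 and 5. In 27 blocks of 500 transcript numbers, over 50% were at 0 in any library, and all of these blocks meet this in the female. Without them, the counts at 1 RPKM were 800 in the male, 384 in the female and 504 in the tetrasporophyte. This choice bears on 1 side. Of the 2037 male transcripts, 846 were listed at exactly 0 in both other libraries. The matching counts at exactly 0 are fixed by the listing rule for the female and the tetrasporophyte and were not compared.

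**Figure D2:**
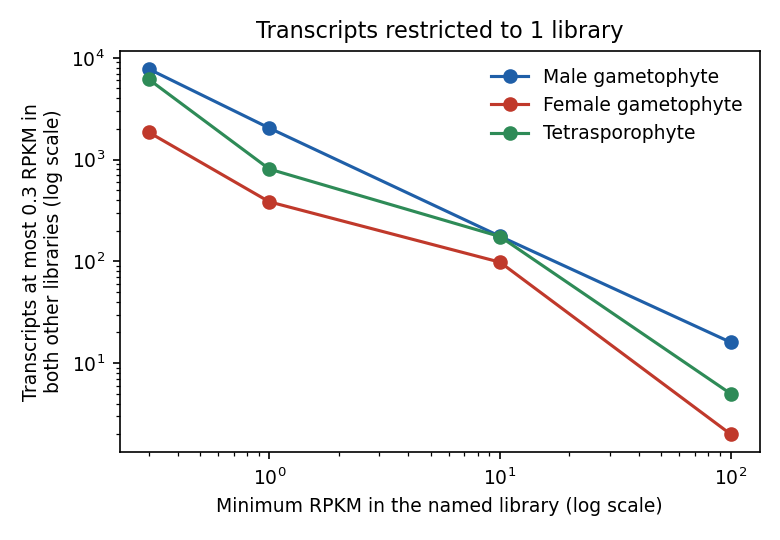
Number of transcripts (log scale) that reach the RPKM on the x axis (log scale: 0.3, 1, 10 and 100) in the named library and are at most 0.3 RPKM or missing in both others. At 1 RPKM the male has 2037, the tetrasporophyte 806 and the female 384, and at 10 RPKM the male and the tetrasporophyte have 176 and 175. The level of 0.3 RPKM equals the limit for the other libraries, so its points can include transcripts barely apart.

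Some transcripts were abundant in 2 libraries and nearly absent from the third. At 10 RPKM or more in male and tetrasporophyte and at most 0.3 RPKM in the female there were 46 transcripts. The corresponding count for female and tetrasporophyte, with the male at most 0.3 RPKM, was 39. For both gametophytes, with the tetrasporophyte at most 0.3 RPKM, it was 92. No listing rule removes any of these, since each is above 0.3 RPKM in a library of both listings. At exactly 0 in one library and at least 1 RPKM in both others there were 238 transcripts for the female, 179 for the tetrasporophyte and 43 for the male, of 15363, 14817 and 14545 transcripts at 1 RPKM or more in both others.

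Zeros were also unevenly placed along the transcript numbers. In the female, no more than 1.32% of any block of 500 from number 39000 onward was at 0, but every listed transcript between 36000 and 38499 was. A transcript of that listing at 0 in the female is never at 0 in the male, since the higher of the 2 is at least 0.3 RPKM.

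**Figure D3:**
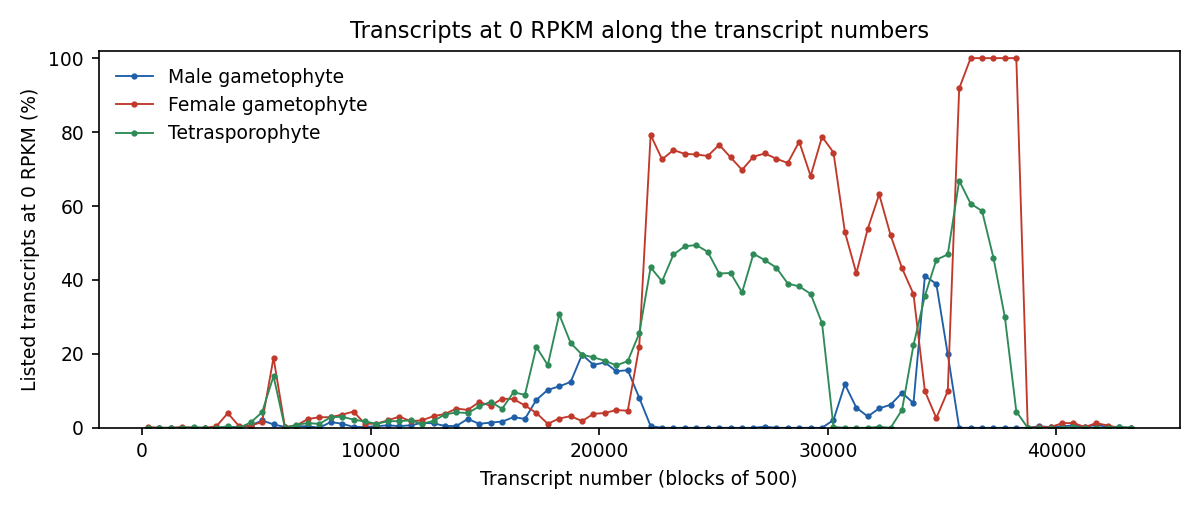
Percentage of listed transcripts at 0 RPKM in blocks of 500 consecutive transcript numbers, for each library, over blocks with at least 20 listed transcripts. The female reaches 100% between numbers 36000 and 38499, where the male can only be at 0%, since the listing holds no transcript below 0.3 RPKM in both.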

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

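The tests in this part were all chosen after the results were seen. In data that the main pairwise comparisons leave out, 6086 transcripts were listed for the tetrasporophyte alone, of which 800 reached 1 RPKM, 175 reached 10 RPKM, 5 reached 100 RPKM and the highest stood at 222.52 RPKM. They drew attention because the main fold comparisons leave them out and their values lie above 0. They do enter the fold counts with missing values set to 0.3 RPKM and the counts of transcripts restricted to the tetrasporophyte, where they make up 800 of the 806 at 1 RPKM. Together they held 1.93% of the summed tetrasporophyte RPKM.

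The male library held more transcripts restricted to it at 1 RPKM than the female library (2037 against 384). If the steps of the low values are those of equal reads, the female library held 1.12 times the male's reads. Under that assumption, which was not tested, deeper sequencing of the male library is argued against. Median-of-ratios scaling did not remove the difference, with 1797 against 435 transcripts, a ratio of 4.13. It shifted the log2 ratio of male to female by only -0.28. Larger single scaling factors were not tried, so scaling in general is not decided. A difference between libraries that varies with level was not tested. The median log2 ratio of male to female was 0.51 between 1 and 10 RPKM, 0.02 between 10 and 100 RPKM and -0.16 above that. The listing rule, as read from the values, leaves out only transcripts below 0.3 RPKM in both libraries of a listing, so it removes none of the transcripts counted here. RNA of another organism in the male culture stays open: 41.5% of the 2037 were at exactly 0 in both other libraries, and without sequences neither this share nor the rest can be assigned. Male-specific expression, which the design names, also stays open and was not tested, as does chance variation between single cultures. The way the assembly was built, taken up in the next paragraph, was not tested either. At 10 RPKM the counts were closer, 176 in the male and 98 in the female.

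Transcripts at 0 RPKM in the female were not spread evenly along the transcript numbers. In blocks of 500 numbers with at least 20 listed transcripts, the share at 0 in the female ran from 0 to 100%. The SD between the 87 blocks was 35.0 percentage points against at most 4.81 in 1000 shuffles, so zeros placed at random along the numbers are argued against. The shuffles do not allow for level, which also varied along the numbers. In the 27 blocks with over 50% at 0 in the female, the male median was 0.57 RPKM, against 6.22 RPKM elsewhere. Of the 2037 transcripts restricted to the male, 1237 lay in the 27 blocks with over 50% at 0 in the female, as did 52 of the 176 at 10 RPKM. Choosing blocks by zeros in the female favours such transcripts, so these shares are no test. Outside the blocks the counts were 800 in the male and 384 in the female, but this choice bears on 1 side. Runs with more zeros in the male than in the female were kept. From 17000 to 21499, 7.57 to 19.8% per block were at 0 in the male and 1.09 to 4.82% in the female. A candidate explanation, not tested, is that runs of numbers were added to the assembly from 1 library at a time.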

How the results depend on the processing

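No paired analysis was possible because each life stage has 1 library, and leaving out replicates was not possible for the same reason. The order within each pair (more transcripts higher in the male than in the female or the tetrasporophyte, and more higher in the tetrasporophyte than in the female) held in all 9 alternatives, of which setting missing values to 0.3 RPKM was chosen after seeing the data. Leaving out the blocks of numbers rich in zeros was not tried on these counts. Setting missing values to 0.3 RPKM could not change the counts between the sexes, whose listings hold the same transcripts. With that setting, transcripts lower in both gametophytes than in the tetrasporophyte, which are also those higher in the tetrasporophyte than in each of the others, numbered 637 instead of 307, and those highest in the female 306 instead of 134. Values below follow the order higher in male and female, in male and tetrasporophyte, in female and tetrasporophyte for the 3 pairs, then higher in both gametophytes, in the tetrasporophyte, in the male and in the female. No cause of the changes below was tested, and the reasons given follow from how a setting is built. At 2-fold they were 5109 and 1777, 4431 and 2375, 1818 and 3476, then 884, 1374, 3287 and 616. At 8-fold they were 803 and 343, 710 and 277, 290 and 332, then 165, 98, 425 and 44. A pseudocount of 0.1 gave 4150 and 1033, 3510 and 1037, 1024 and 1966, then 594, 481 and 2673, with the female count within 1.5 times. A filter of 10 RPKM moved 4 counts by over 1.5 times: higher in male than female to 1117, in male than tetrasporophyte to 880, in both gametophytes to 191 and highest in the male to 575. Keeping only transcripts above 0 in all 3 libraries gave 408 higher in female than male, 1044 higher in male than tetrasporophyte and 656 highest in the male. Scaling each sum to 1000000, which raises every value against the fixed pseudocount and filter, gave 1652 highest in the male. Median-of-ratios scaling moved no count by over 1.5 times, and the share higher in the male of those apart between the sexes was 68.0% under it against 74.1%. Dropping the filter changed no count, since no transcript below 1 RPKM can be 4-fold apart with a pseudocount of 1. Whether more transcripts were higher or lower in both gametophytes depended on the setting, as 335 against 307 became 884 against 1374 at 2-fold. Transcripts counted as restricted to 1 library at 0.3 RPKM numbered 7760 (male), 1853 (female) and 6142 (tetrasporophyte). That level equals the limit for the other libraries, so these counts can include transcripts barely apart. At 10 RPKM the counts were 176, 98 and 175, and at 100 RPKM 16, 2 and 5. Without the blocks of numbers with over 50% at 0 in any library, an alternative chosen after seeing the data that bears on 1 side since all of them meet it in the female, those at 1 RPKM numbered 800 (male), 384 (female) and 504 (tetrasporophyte). The 846 male transcripts at exactly 0 in both others were 3568 at any value above 0 and 32 at 10 RPKM. Spearman correlations at 10 RPKM, a level added after seeing the data, were 0.5987, 0.5852 and 0.6641. With missing values set to 0.3 RPKM and lower values raised to it, also added after seeing the data, they were 0.7859, 0.7554 and 0.8074. The alternatives for gene lists were not run, since no transcript is named. None of the 12 named log2 ratios changed sign, but they were chosen as the largest, so this is no evidence of robustness. Scaling moved them by up to 1.06 and the pseudocount of 0.1 by up to 2.81. Unknown read totals limit every value near 0.3 RPKM, where a few reads may decide the fold.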

Other observations

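The tests in this part were chosen after the results were seen. The share at 0 differed between libraries along the transcript numbers. Between numbers 36000 and 38499, every listed transcript was at 0 in the female, at male medians of 0.36 to 0.49 RPKM. Between 22000 and 29999, 68.1 to 79.2% per block of 500 were at 0 in the female and 28.3 to 49.4% in the tetrasporophyte, but at most 0.477% in the male. In the 2 blocks between 34000 and 34999, 41.1% and 38.9% were at 0 in the male, 9.90% and 2.65% in the female, and 35.7% and 45.5% in the tetrasporophyte. From 39000 onward, at most 1.32% of any block was at 0 in any of the 3 libraries. No listed transcript is at 0 in both male and female, since one of the 2 always reaches 0.3 RPKM in their listing, so a high share at 0 in one limits the share in the other.

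Of the transcripts with the largest ratios, 2 with consecutive numbers had opposite patterns between the sexes. ISGT_41943 had 320 RPKM in the female and 1.20 RPKM in the male, and ISGT_41944 had 0.43 RPKM in the female and 691 RPKM in the male, while both were abundant in the tetrasporophyte (986 and 294 RPKM). Without sequences it is not known whether they are related.

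Transcripts of 1 sex that the tetrasporophyte shares could come from regions that only 1 sex carries, and a diploid tetrasporophyte would then hold 1 copy where a gametophyte holds 1 per haploid genome. Under that hypothesis the ratio of tetrasporophyte to gametophyte would lie near -1 on the log2 scale. For the 46 transcripts of male and tetrasporophyte the median log2 ratio was -0.76 (95% bootstrap interval -0.96 to -0.48), with 38 of 46 below 0, against -0.22 to 0.24 for the central 95% of 2000 random sets matched on male level. For the 39 of female and tetrasporophyte it was -0.53 (-0.98 to -0.10), with 28 of 39 below 0, against -0.14 to 0.27 for matched sets. The intervals resample transcripts, which are not independent replicates, and hold no spread between cultures or libraries. All members had at least 10 RPKM in the tetrasporophyte, as had the matched sets, so a ratio of -1 was out of reach for the 12 male and 18 female members under 20 RPKM in the gametophyte, and the distance of the medians from -1 is not evidence. Both medians lie below the matched sets. These sets were not restricted to transcripts nearly absent from the other sex, so the selection itself may lower the medians against them. The hypothesis is left undecided: a lower expression in the spore-bearing stage would give the same direction, and there is 1 library per stage.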
